A study of Mus musculus with 4 samples.

How the data were processed

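The 4 libraries are droplet-based single-cell RNA sequencing libraries, 1 per mouse, of heart cells other than cardiomyocytes that were sorted by flow cytometry for a red fluorescent reporter. All 4 carry the same group label and separate animal numbers, so they form 1 group of 4 animals. The animal is the replicate in the tests between classes, where cells were not treated as replicates. Exact intervals on shares of cells do count single cells, in places pooled over the animals, and leave out the spread between animals.

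Per the submitters' processing notes, the reads were processed with Cell Ranger, and the genome build named there is mm10; the version, the annotation release and the barcode-calling settings are not given in the sources used here. Each library came as 2 deposited matrices of raw UMI counts per gene and barcode, 1 against the mouse genome with 28692 genes and 1 against the human build hg19 with 33354 genes. The values are whole numbers and not normalised, so the authors' counts were used as they stand. A UMI is a molecular identifier that lets copies of 1 captured RNA molecule be counted once. Barcodes outside these filtered matrices were not analysed here.

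Mouse barcodes were kept if they had at least 200 detected genes and at most 25% of their UMIs from mitochondrial genes. Each kept cell was scaled to 10000 UMIs and log-transformed, and 2000 variable genes, 20 principal components and 15 neighbours were used for Leiden clustering at resolution 0.8 and seed 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). So that no gene was tested between clusters it had helped to form, the genes were split before the data were examined. Tested genes can still vary together with clustering genes across the same cells, so the split does not make the tests independent of the classes. Preset cell type markers, and genes outside the lists whose symbol had an even checksum, were used for clustering (14304 genes, of which those in fewer than 3 cells were dropped). Other genes with an odd checksum and the members of 16 preset gene lists were used for tests (14388 genes).

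Each cluster was matched to the 1 of 14 preset marker lists with the most markers detected in at least 25% of its cells. It took that name when at least 3 markers were so detected and no other list had more members among its top 10 genes by fold over the other cells, computed on UMIs scaled to the usual CPM total with 20 CPM added to both sides. A cluster under 1/3 of the usual depth of its animals with no marker of its own in that top 10 stayed unnamed. That top 10 was ranked over all genes, the tested ones included. The marker lists stood for fibroblasts, endothelial cells, lymphatic endothelial cells, pericytes, smooth muscle, cardiomyocytes, macrophages or monocytes, T or NK cells, B cells, granulocytes, erythroid cells, Schwann cells, mesothelial or epicardial cells, and adipocytes. Doublets were not removed in the main analysis; calls from Scrublet, made per animal, were left out as an alternative. Scrublet called 27 cells, namely 4, 17, 4 and 2 in animals 1 to 4, which leaves 15 of the 32 kept cells of animal 2. Shares of cells carry exact Clopper-Pearson 95% intervals, and a count of 0 carries the limit that 3 counts would give. These intervals and limits cover counting error only. Shares of cells with a Twist2 UMI were also computed after each cell had been thinned to 2000 UMIs.

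UMI counts were summed per animal and class wherever a class held at least 10 cells in an animal, and pairs of classes with such sums in at least 3 animals were compared. With 1 animal left out, 2 animals were allowed, so fits against macrophage or monocyte-like cells without animal 1, 3 or 4 hold 2 animals. Each fit held the sums of its 2 classes only, with the animal as a block, because both sums of an animal come from the same animal and library. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Fold changes are first class minus second class on the log2 scale, each with a standard error taken as its size over the square root of F. Where 1 class had no UMI of a gene, the fold is a lower limit against 3 UMIs over the class. Where it had 1 to 3, the ratio of summed CPM is given with its exact 95% counting interval.

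The gene lists covered extracellular matrix (ECM) proteins, basement membrane, complement, the IGF axis, mesenchymal and cardiac transcription factors, vascular transcription factors and signalling, fatty acid handling, chemokines and cytokines, MHC class I and II, interferon response, immediate early and stress genes, progenitor-associated genes, TGF-beta and BMP signalling, Wnt signalling, the cell cycle, and mitochondrial oxidative phosphorylation. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with the other tested genes. Fry asks whether the members of a list move, on balance, one way. The genes named were, for each pair, the 10 with the largest change in each direction among those past the threshold with the same direction in every animal and at least 100 CPM in the higher class. Up to 3 members of each list with the highest mean level were added, with Twist2, Twist1, Ly6a and tdTomato always included. List members outside this rule are named only where a count is small, and they were chosen after their values were seen. Ccl19, Ccl21a and Ltbp4 each matched 2 identifiers and Cd29 matched 0, so Cd29 was left out of its list. Ccl19 and Ltbp4 were left out of the list tests, but both of their identifiers count in the shares of UMIs taken by lists. Ccl21a, a lymphatic endothelial marker, was kept with both identifiers among the clustering genes, in naming and in marker shares. Tcf4 was placed in the Wnt list, but its identifier is that of the bHLH factor E2-2 and not of the Wnt effector called TCF-4, whose gene is Tcf7l2, so it is not read as a Wnt gene.

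The testing step was checked on simulated negative binomial counts with the depths, mean levels and common dispersion of the real class sums. With 190 of 1035 genes changed in the simulation of fibroblast-like against endothelial-like cells, 63.3% were recovered at a log2 change of 1 and 100% at 2 and at 3, with 4 false calls. For fibroblast-like against macrophage-like cells, 77.4% of changes of log2 1 were recovered (1068 genes, 193 changed, 6 false calls). The corresponding figure for endothelial-like against macrophage-like cells was 72.1% (944 genes, 191 changed, 4 false calls). The simulation gave every gene the same dispersion and added an animal effect shared by both classes. It changed a smaller part of the genes than was called in the real data. Changed genes dropped by the low-count filter were not scored, so recovery in the real data may be poorer.

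Alternatives fixed before the data were examined were other cell filters, clustering resolutions, numbers of components, centring of each animal, clustering on all genes, removal of called doublets, DESeq2 size factors, the DESeq2 Wald test (DESeq2 1.42.0), no low-count filter, no replicate block, sums of at least 5 cells, and each animal left out in turn. Leaving out cells with over 50% haemoglobin UMIs was added after the data had been seen. Coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 names, and 28339 of the 28692 mouse gene identifiers were found in it. Coordinates were found for 105 of 107 named genes. Counting could split reads between near-identical copies, so Hspa1a and Hspa1b, H2-K1 and H2-D1, and Bcl2a1a, Plac9b and Lilr4b with their relatives, are uncertain. Whether antisense or overlapping genes share counts is not given in the sources used here.

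Depth limits what these libraries can show. The animals gave 99, 32, 57 and 58 kept cells with 805649, 191229, 371148 and 446894 UMIs, so values for animal 2 rest on the least data. Animal 2 has 5 macrophage or monocyte-like cells and entered comparisons of class sums with that class only where sums of at least 5 cells were allowed.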

Results

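Single-cell RNA sequencing was performed on heart cells other than cardiomyocytes from 4 mice aged 9 weeks. The mice carried a tamoxifen-activated Cre recombinase named for Twist2, a basic helix-loop-helix transcription factor of mesenchymal cells, together with a tdTomato reporter at the Rosa26 locus. In this system a cell in which the recombinase was active during tamoxifen treatment, and its descendants, carry the red fluorescent protein. Cells positive for it were sorted 10 days after tamoxifen and profiled on the 10x platform, with 1 library per animal. All 4 libraries belong to a single group, so the questions the data can address are which cells the labelled population held and how these cells differed from one another. Cells without the label were not analysed here.

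The mouse-genome matrices held 128, 106, 83 and 90 barcodes for animals 1 to 4, with 883299, 272131, 405335 and 525405 UMIs. Of these 407 barcodes, 246 (60.4%) passed the cell filter, namely 99, 32, 57 and 58. The kept cells had a median of 7281 UMIs and 2083 detected genes, and the medians per animal were 7987, 4742.5, 6656 and 7293 UMIs. Most of the barcodes left out, 145 in all, had over 25% of their UMIs from mitochondrial genes. These had a median of 98.0% mitochondrial UMIs, 883 UMIs and 28 detected genes. They made up 67.0% of the barcodes of animal 2, against 18.8%, 30.1% and 27.8% in animals 1, 3 and 4. A further 14 barcodes that failed the filter carried over 50% haemoglobin UMIs, in counts of 5, 1, 1 and 7 per animal.

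**Figure D1:**
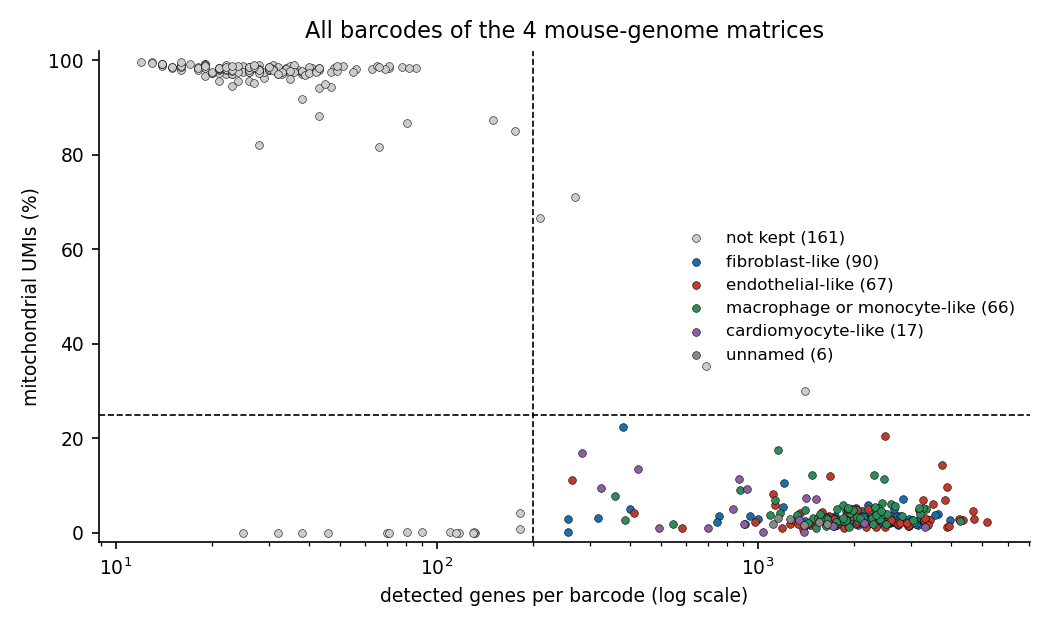
Percent of UMIs from mitochondrial genes against detected genes per barcode (log scale) for all 407 mouse-genome barcodes, coloured by class, with dashed lines at 25% and at 200 genes. The 145 barcodes over 25% mitochondrial UMIs sit mostly near 98.0% with a median of 28 detected genes, apart from the 246 kept cells.

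Fibroblast-like, endothelial-like, macrophage or monocyte-like and cardiomyocyte-like cells were found among the labelled cells. Fibroblast-like cells, marked by collagen genes and by Pdgfra and Dcn, numbered 90 and made up 35.8% ± 2.39 of the kept cells (SD, n = 4 animals). Endothelial-like cells, marked by Pecam1 and Cdh5 among others, numbered 67 and made up 28.3% ± 9.57. Macrophage or monocyte-like cells, which carried the complement genes C1qa, C1qb and C1qc, numbered 66 and made up 25.1% ± 6.39. Cardiomyocyte-like cells, with the sarcomere genes Tnnt2, Myl2 and Tnni3 leading, numbered 17 and made up 7.90% ± 5.38, although the sorted population is labelled as free of cardiomyocytes.

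The share of fibroblast-like cells was 39.4%, 34.4%, 35.1% and 34.5% in animals 1 to 4, with exact 95% intervals of 29.7 to 49.7%, 18.6 to 53.2%, 22.9 to 48.9% and 22.5 to 48.1%. Endothelial-like shares were more spread, at 29.3%, 40.6%, 17.5% and 25.9%. Macrophage or monocyte-like shares were 29.3%, 15.6%, 28.1% and 27.6%. Cardiomyocyte-like cells ranged from 1 of 99 cells in animal 1 (1.01%, interval 0.0256 to 5.50%) to 7 of 57 in animal 3 (12.3%, interval 5.08 to 23.7%). The fibroblast-like share exceeded the endothelial-like share in 3 of 4 animals, by 7.50 ± 9.97 percentage points on average. The exact two-sided sign-flip test gave p = 0.25, but with 4 animals it cannot go under 0.05, so it decides nothing here. The mean was 12.1 points without animal 2 and 3.01 without animal 3, and without Scrublet calls it was 12.0 ± 4.18, higher in 4 of 4 animals. Its sign turned when at least 500 detected genes were required (−7.93 points) and at a clustering resolution of 1.2 (−7.18 points).

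The endothelial-like class joined 2 clusters. The larger one, of 52 cells, was led by Fabp4, Gpihbp1 and Cldn5. A cluster of 15 cells was led instead by Cytl1, Vwf, Cpe, Igfbp5, Plvap and Npr3, with 8 endothelial markers detected, and 9, 1, 4 and 1 of its cells came from animals 1 to 4. A cluster of 6 cells remained unnamed because 2 of the T or NK markers were detected in it; its leading genes included Sh2d2a and Trac, of which Trac encodes the constant region of the T cell receptor alpha chain. No cluster took the name of the other 10 marker lists. In the fibroblast-like and endothelial-like cells, pooled over animals, pericyte markers took 0.0363% and 0.0538% of non-mitochondrial UMIs, smooth muscle markers 0.00562% and 0.00744%, lymphatic endothelial markers 0.0142% and 0.00951%, Schwann markers 0.0293% and 0.00269%, mesothelial or epicardial markers 0.000296% and 0.0283%, and adipocyte markers 0.0114% and 0.0101%. The endothelial-like values rest on animal 4 for pericyte markers (0.145%, against 0.00274 to 0.0359% in the others) and on animal 1 for mesothelial or epicardial markers (0.0577%, against 0 to 0.00577%). Smooth muscle markers were also highest in animal 4 (0.0173%, against 0.00144 to 0.00685%) and lymphatic endothelial markers in animal 1 (0.0159%, against 0 to 0.00959%). In the macrophage or monocyte-like cells, B cell markers took 0.0109% and granulocyte markers 0.00102%. In the unnamed cluster, T or NK markers took 0.0846% (0.284%, 0.173% and 0.0387% in animals 1 to 3) and B cell markers 0.129%, all of it from animal 3 (0.177%). Erythroid markers took 0.00455% in the endothelial-like class and 2.28% in the fibroblast-like class, namely 11.1% in animal 3 and 0.00206 to 0.00283% in the others. A barcode of animal 3 that clustered with the fibroblast-like cells had 256 detected genes and 96.4% haemoglobin UMIs. Its 16122 UMIs are part of the 144008 of the fibroblast-like sum of animal 3, which lowers the CPM of other genes there.

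**Figure D2:**
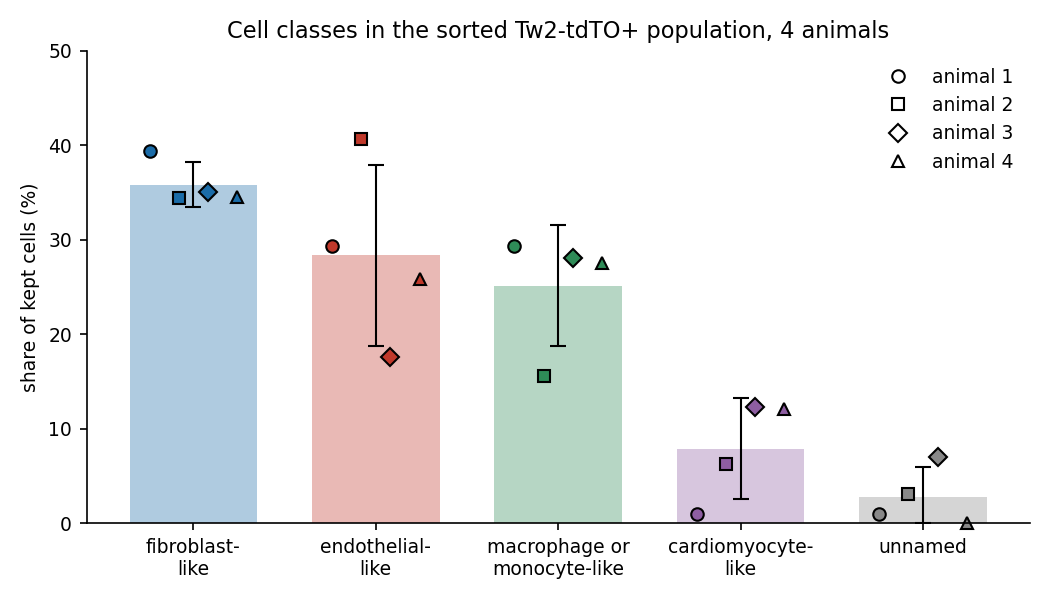
Percent of kept cells in each class, with a point per animal, bars for the mean and whiskers for the SD over 4 animals. Fibroblast-like cells averaged 35.8%, endothelial-like cells 28.3%, macrophage or monocyte-like cells 25.1%, cardiomyocyte-like cells 7.90% and unnamed cells 2.79%.

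Twist2, the gene whose activity the label is meant to record, was detected in few cells, and nearly all of its UMIs lay in fibroblast-like cells. Its gene (ENSMUSG00000007805) lies on the plus strand of chromosome 1, from 91801461 to 91848028 on mm10. Among the 246 kept cells it gave 8 UMIs, of which 7 came from 7 of 90 fibroblast-like cells (7.78%, exact 95% interval 3.18 to 15.4%). By animal these were 5 of 39, 1 of 11, 0 of 20 and 1 of 20 cells, so the pooled share rests mostly on animal 1. A Twist2 UMI was found in 1 of 67 endothelial-like cells (1.49%, 0.0378 to 8.04%). None was found in 66 macrophage or monocyte-like cells, where 3 counts would give a share of cells with a UMI of 4.55%. Nor was any found in 17 cardiomyocyte-like cells, where 3 counts would give 17.6%. The exact 95% intervals, as used for the other classes, reach 5.44% and 19.5% there. The median depths of the 4 classes were 7667, 6703, 8019 and 2924 UMIs. The intervals of the fibroblast-like and endothelial-like shares overlap, but they pool cells over the animals. The difference between these shares was not tested. After thinning to 2000 UMIs, 3 of 82 fibroblast-like cells kept a Twist2 UMI (3.66%), and 0 cells of the other classes did.

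Per animal, Twist2 stood at 7.45, 5.23, 0 and 2.24 CPM (UMIs scaled to a common total) over all kept cells, a mean of 3.73 ± 3.28 (SD, n = 4). The related factor Twist1 gave 11 UMIs, 6 in fibroblast-like and 5 in endothelial-like cells. Neither gene had enough UMIs to be tested between classes. The mouse matrices hold no entry under the name tdTomato, so the reporter itself was not analysed here.

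Of the gene lists tested, fibroblast-like cells were higher than endothelial-like cells in matrix, basement membrane and complement genes and lower in vascular, lipid-uptake, antigen presentation and interferon genes at a preset inter-gene correlation. None of these 7 calls held with an estimated correlation (adjusted p = 0.182 to 0.343). For basement membrane genes that estimate was −0.0491, below the preset 0.01, so the loss of that call does not show that correlated genes had made it. Fry, which does not compare a list with other genes, called all 7 (fry adjusted p = 0.00207 to 0.0150). Clec3b, which encodes the plasminogen-binding protein tetranectin, had 1327 ± 148 CPM in fibroblast-like cells and 38.0 ± 42.1 in endothelial-like cells (SD, n = 4 animals), a log2 fold change of 5.15 ± 0.46 (SE; edgeR adjusted p = 9.58e-05). The elastic fibre component Mfap5 was higher by 4.82 ± 0.36 on the log2 scale (adjusted p = 7.88e-05). In the other direction, the fatty acid transporter Cd36 had 59.2 ± 46.0 CPM in fibroblast-like cells and 1611 ± 558 in endothelial-like cells (log2 −4.76 ± 0.40, adjusted p = 9.58e-05). Gpihbp1, which anchors lipoprotein lipase to capillary endothelium, was lower by a log2 change of −5.15 ± 0.67 (adjusted p = 0.000342). The same direction in every animal was a condition for naming Clec3b, Mfap5 and Gpihbp1, so it adds nothing for them. Cd36, named from its list, also ran the same way in all 4 animals. Clec3b, Mfap5, Cd36 and Gpihbp1 took no part in the clustering, but Clec3b, Mfap5 and Gpihbp1 were among the top genes ranked when clusters were named.

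ECM protein genes were higher in fibroblast-like cells almost throughout: of 27 measured, 25 were higher and 1, the metalloproteinase inhibitor Timp3, was lower, with the same counts adjusted over the list alone (camera adjusted p = 2.63e-16). With an estimated correlation the adjusted p = 0.182. The proteoglycan Bgn changed by log2 2.46 ± 0.38 and the microfibril gene Mfap4 by 4.90 ± 0.57, while Timp3 changed by −0.85 ± 0.19. Fibroblast markers, which were not tested, took 5.39% of non-mitochondrial UMIs in the fibroblast-like class and 0.335% in the endothelial-like class. Of 12 basement membrane genes, 6 were higher and 0 lower, and the counts were equal adjusted over the list alone (camera adjusted p = 0.0165; adjusted p = 0.229 with an estimated correlation). The type IV collagen gene Col4a1 was not told apart between the classes (log2 −0.18 ± 0.21, adjusted p = 0.563), nor was Sparcl1 (0.52 ± 0.21, adjusted p = 0.0898).

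Complement genes were also higher in fibroblast-like cells, with 4 of 5 past the threshold, 5 adjusted over the list alone, and 0 lower (camera adjusted p = 0.00886; adjusted p = 0.343 with an estimated correlation). Serping1, the C1 inhibitor, had 1265 ± 201 against 87.8 ± 79.2 CPM (log2 3.96 ± 0.49). C3, the central complement protein, was higher by 2.59 ± 0.72, with endothelial-like C3 at 346 CPM in animal 1 and 0 to 39.5 in the others, and by 4.29 ± 0.55 without animal 1. In the IGF axis, 4 of 6 genes were higher and 1, Igfbp5, was lower, also adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.0514; adjusted p = 0.260 with an estimated correlation). The protease gene Htra3 rose by 3.31 ± 0.31 and the binding protein gene Igfbp4 by 2.14 ± 0.26 on the log2 scale. Of 4 measured mesenchymal and cardiac transcription factors, Tbx20, known from heart development, was higher by 2.79 ± 0.46 and Zeb2 by 1.46 ± 0.48, the 2 calls being unchanged adjusted over the list alone (camera adjusted p = 0.183).

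Vascular transcription factors and signalling genes were lower in fibroblast-like cells in 10 of 13 cases, 11 adjusted over the list alone, and higher in 0 (camera adjusted p = 5.07e-08; adjusted p = 0.182 with an estimated correlation). Flt1, a receptor for VEGF, had 16.9 ± 15.9 against 795 ± 150 CPM (log2 −5.20 ± 0.56). The Notch ligand Dll4 gave 0 UMIs in the fibroblast-like sums and 55 in the endothelial-like sums, at least 25.4-fold lower against 3 UMIs over the class. Endoglin, encoded by Eng, changed by −2.54 ± 0.31. All 6 measured fatty acid handling genes were lower, also adjusted over the list alone (camera adjusted p = 4.03e-06; adjusted p = 0.182 with an estimated correlation). The lipase gene Lpl changed least among them, by −0.90 ± 0.25. Endothelial markers took 1.59% of non-mitochondrial UMIs in the endothelial-like class and 0.0543% in the fibroblast-like class.

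Antigen presentation and interferon genes were lower in fibroblast-like cells. All 5 measured MHC genes were lower, also adjusted over the list alone, with B2m, the light chain of class I molecules, at log2 −1.07 ± 0.20 (camera adjusted p = 0.00886; adjusted p = 0.260 with an estimated correlation). Of 7 interferon response genes, 5 were lower and 0 higher, also adjusted over the list alone, with the membrane protein gene Bst2 at −1.81 ± 0.36 (camera adjusted p = 0.0376; adjusted p = 0.343 with an estimated correlation). Chemokines and cytokines were divided: Ccl7, Cxcl1, Ccl2 and Csf1 were higher, Cxcl12 and Kitl were lower, and 4 higher and 3 lower were counted adjusted over the list alone (camera adjusted p = 0.365). The neutrophil attractant Cxcl1 differed by 3.31 ± 0.54, with 3809 ± 1677 CPM in fibroblast-like cells.

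Immediate early and stress genes went both ways, with 4 of 16 higher, 2 lower, and 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.305). The lower ones were the heat shock genes Hspa1a (log2 −1.54 ± 0.21) and Hspa1b, near-identical copies whose counts cannot be fully separated. Ly6a, which encodes the stem cell antigen Sca-1, was lower in fibroblast-like cells, at 491 ± 160 against 1555 ± 667 CPM (log2 −1.48 ± 0.21, adjusted p = 0.000542). Cd34 was higher, by 1.01 ± 0.23, and the progenitor-associated list of 3 genes with 1 in each direction, also adjusted over the list alone, did not pass (camera adjusted p = 0.550). Among 9 TGF-beta and BMP genes, Tgfbr3 and Tgfbr2 were higher and Id1 and Tgfb1 lower, the same adjusted over the list alone (camera adjusted p = 0.550); the list's median was just above 0 and its mean and its test below it. The BMP-responsive gene Id1 changed by −3.28 ± 0.26. In oxidative phosphorylation 3 of 15 genes were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.285). The Wnt inhibitor Sfrp1, with 3 UMIs in the endothelial-like sums, was higher by a ratio of 30.1 (counting interval 10.1 to 148), and no other Wnt gene of the list was measured. Tcf4, which encodes the bHLH factor E2-2, was lower, by log2 −0.81 ± 0.25. The 1 measured cell cycle gene, Pcna, was lower at −1.12 ± 0.34.

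In all, 190 of 1045 tested genes were higher and 168 lower in fibroblast-like cells (edgeR quasi-likelihood test with the animal as a block, adjusted p under 0.05). Without animal 4 the number of higher genes was 121, with 834 genes tested, and the calls of C3 (adjusted p = 0.157), Zeb2 (0.153), Sparc (0.145), Tcf4 (0.0972) and Mgp (0.112) and of the interferon list (0.101) were lost, among others. Without animal 3, those of Timp3 (adjusted p = 0.0624), Lpl (0.12) and Pcna (0.0632) were among those lost.

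**Figure D3:**
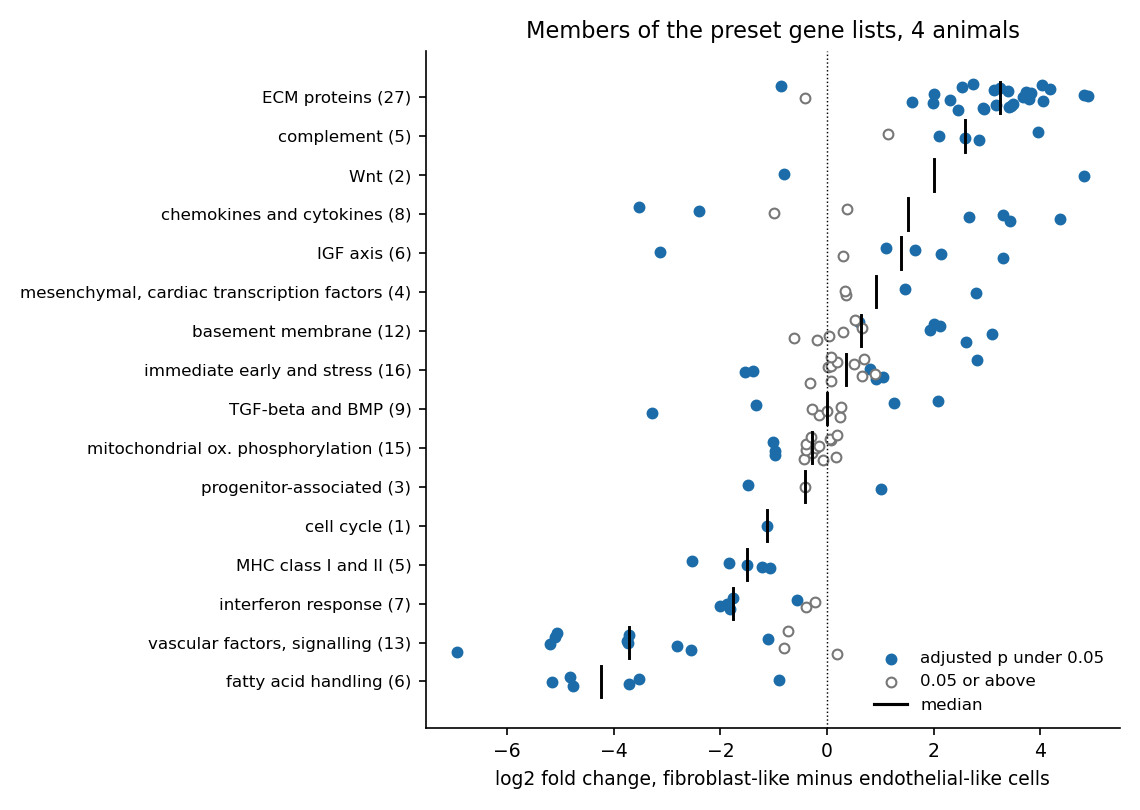
Log2 fold change, fibroblast-like minus endothelial-like cells, of each measured member of the gene lists, with lists down the side, filled points for adjusted p under 0.05 and a bar at each median. ECM protein genes lie mostly above 0, with 25 of 27 higher, and the 6 fatty acid handling genes all lie below it.

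Against macrophage or monocyte-like cells, fibroblast-like cells were higher in matrix, basement membrane, complement and IGF genes and lower in MHC genes. None of these list calls held with an estimated correlation (camera adjusted p = 0.374 to 0.429). Each was called by fry, which does not compare a list with other genes (fry adjusted p = 0.00548 to 0.0199). The chemokine and cytokine list was not called: 4 of 7 genes were lower, and Csf1, Il6 and Cxcl1 were higher. Clec3b had 1397 ± 63.1 CPM in fibroblast-like cells (SD, n = 3 animals) and 0 UMIs in the macrophage sums, at least 219-fold higher against 3 UMIs over the class. Cd74, the invariant chain of MHC class II, stood at 59.8 ± 80.6 in fibroblast-like and 10935 ± 1956 CPM in macrophage or monocyte-like cells (log2 −7.64 ± 0.49, edgeR adjusted p = 8.1e-07). Cxcl2, a neutrophil attractant, stood at 373 ± 407 against 20880 ± 4585 (log2 −6.25 ± 0.46, adjusted p = 1.27e-06). The chemokine gene Ccl24 had no UMI in the fibroblast-like sums and was at least 55.2-fold lower.

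Of 28 ECM protein genes, 27 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 6.35e-18; adjusted p = 0.384 with an estimated correlation). Bgn differed by log2 7.25 ± 0.31 and the matrix gene Mgp by 6.25 ± 0.44. Fibroblast markers took 0.0356% of non-mitochondrial UMIs in the macrophage class, and macrophage or monocyte markers took 2.42% there against 0.0179% in the fibroblast-like class. All 12 basement membrane genes were higher, also adjusted over the list alone, with Sparc at 5.80 ± 0.33 (camera adjusted p = 9.1e-10; adjusted p = 0.384 with an estimated correlation). All 6 complement genes were higher, the count being equal adjusted over the list alone, with Serping1 higher by a ratio of 194 (counting interval 66.3 to 945) over 3 UMIs in the macrophage sums (camera adjusted p = 0.000649; adjusted p = 0.429 with an estimated correlation). In the IGF axis 5 of 6 genes were higher and 0 lower, or 5 and 1 adjusted over the list alone, with Igfbp7 at 6.54 ± 0.31 (camera adjusted p = 0.000203; adjusted p = 0.374 with an estimated correlation).

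All 9 MHC genes were lower in fibroblast-like cells, also adjusted over the list alone (camera adjusted p = 2.68e-07; adjusted p = 0.374 with an estimated correlation). Interferon response genes were lower in 5 of 8 cases and higher in 0, or 5 lower and 2 higher adjusted over the list alone, with Isg15 at −4.34 ± 0.31 (camera adjusted p = 0.0315; adjusted p = 0.384 with an estimated correlation). Immediate early and stress genes were higher in 11 of 16 cases and lower for Atf3 and Ier3, or 11 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0216; adjusted p = 0.460 with an estimated correlation). Jund differed by 0.97 ± 0.16.

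Other lists did not pass in this pair. Chemokines and cytokines counted 3 of 7 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.486), and TGF-beta and BMP genes 7 of 12 higher and 2 lower, also adjusted over the list alone (0.113). Id3 was higher by 3.19 ± 0.27 and Id2 lower, at −1.43 ± 0.24. All 4 vascular genes were higher in fibroblast-like cells, the same adjusted over the list alone, with Eng at 1.99 ± 0.44 (camera adjusted p = 0.0966). Of the progenitor-associated genes, Cd34 and Ly6a were higher and Cd44 lower among 4, with 3 higher adjusted over the list alone (camera adjusted p = 0.142). Ly6a differed by 3.28 ± 0.40. Of the mesenchymal and cardiac transcription factors, Tbx20 and Gata6 were higher and Mef2c and Zeb2 lower, also adjusted over the list alone; the median and mean were above 0 while camera's direction was down (adjusted p = 0.866). Oxidative phosphorylation had 0 of 15 higher and 1 lower, Cox5a, also adjusted over the list alone (camera adjusted p = 0.515). Of the Wnt list Sfrp1 was higher, as was Tcf4, the bHLH factor gene; of the fatty acid genes Lpl was higher and Cd36 lower; the 2 measured cell cycle genes, Cenpa and Ccnb2, did not pass.

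The edgeR test called 285 genes higher and 246 lower of 1067 in fibroblast-like cells, over animals 1, 3 and 4. The interferon list lost its call in 6 other settings, among them the fit without animal 1, which holds 2 animals (adjusted p = 0.051), and the fit without the animal block (0.0826). The stress list lost its call with at least 500 detected genes (adjusted p = 0.0894) and with sums of at least 5 cells (0.0845).

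Endothelial-like cells, set against macrophage or monocyte-like cells, were higher in basement membrane, vascular and fatty acid handling genes and lower in MHC genes and in 6 of 8 chemokines and cytokines. None of these list calls held with an estimated correlation (adjusted p = 0.285 to 0.287). Fry, which does not compare a list with other genes, called each of them (fry adjusted p = 0.0143 to 0.0198). Tm4sf1, a membrane protein gene, had 1189 ± 442 CPM in endothelial-like cells (SD, n = 3 animals) and 1 UMI in the macrophage sums, a ratio of 603 with a counting interval of 108 to 23876. The transcription factor gene Sox17 was at least 31.2-fold higher, with 0 UMIs in macrophage or monocyte-like cells. Cd74 was lower by a log2 change of −8.12 ± 0.37 (edgeR adjusted p = 2.31e-06), and Fcer1g, the signalling chain of Fc receptors, had 2 UMIs in endothelial-like and 871 in macrophage or monocyte-like sums, a ratio of 396 with an interval of 109 to 3271.

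All 9 basement membrane genes were higher, also adjusted over the list alone, with Col4a1 at log2 5.12 ± 0.38 (camera adjusted p = 3.02e-07; adjusted p = 0.285 with an estimated correlation). Vascular genes were higher in 10 of 11 cases, also adjusted over the list alone, with Eng at 4.65 ± 0.36 (camera adjusted p = 1.93e-06; adjusted p = 0.285 with an estimated correlation). All 5 fatty acid handling genes were higher, again also adjusted over the list alone, with Gpihbp1 at 4.83 ± 0.57 and Cd36 at 1.99 ± 0.23 (camera adjusted p = 0.000628; adjusted p = 0.287 with an estimated correlation). Endothelial markers took 0.0408% of non-mitochondrial UMIs in the macrophage class. ECM protein genes counted 3 of 7 higher, Bgn, Timp3 and Mgp, and Timp2 lower, the same adjusted over the list alone (camera adjusted p = 0.0230; adjusted p = 0.285 with an estimated correlation).

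MHC genes were lower in 5 of 9 cases, 6 adjusted over the list alone, and higher in 0 (camera adjusted p = 1.46e-05; adjusted p = 0.285 with an estimated correlation). The genes past the threshold were Cd74, H2-Ab1, H2-Aa and H2-Eb1, which belong to class II presentation, and the class I gene H2-D1, while B2m was not told apart (log2 −0.34 ± 0.17, adjusted p = 0.151). Chemokines and cytokines were lower in 6 of 8 cases, and Cxcl12 and Kitl were higher, also adjusted over the list alone (camera adjusted p = 0.00468; adjusted p = 0.285 with an estimated correlation). Ccl2, an attractant of monocytes, changed by −5.85 ± 0.40.

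In the IGF axis Igfbp7, Igfbp5 and Igfbp6 were higher and Igf1 lower of 5 measured, also adjusted over the list alone (camera adjusted p = 0.0317; adjusted p = 0.285 with an estimated correlation). Immediate early and stress genes were higher in 7 of 16 cases, 10 adjusted over the list alone, and lower in 0 (camera adjusted p = 0.0230; adjusted p = 0.648 with an estimated correlation). Ly6a was higher in endothelial-like cells by log2 4.52 ± 0.43, and Cd34 by a ratio of 62.8 (counting interval 21.1 to 307) over 3 UMIs in the macrophage sums. Of 4 progenitor-associated genes, 3 were higher and Cd44 lower, also adjusted over the list alone (camera adjusted p = 0.0741).

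The remaining lists did not pass. Of 5 TGF-beta and BMP genes, Id1, Id3 and Smad7 were higher and Id2 lower, also adjusted over the list alone (camera adjusted p = 0.218), with Id1 at log2 4.19 ± 0.48. Of 10 interferon response genes, Ifitm3 and Ifi27 were higher and Isg15 and Rsad2 lower, also adjusted over the list alone; the median was just above 0 and the mean and the test below it (camera adjusted p = 0.792). Oxidative phosphorylation had 1 of 15 genes higher, Atp5j, and 0 adjusted over the list alone (camera adjusted p = 0.792). Zeb2 was lower and Tcf4 higher, and the 1 measured cell cycle gene, Pcna, did not pass.

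Over the same 3 animals the edgeR test called 175 genes higher and 193 lower of 929 in endothelial-like cells. Without animal 4, in a fit of 2 animals, the chemokine (adjusted p = 0.0822), IGF (0.0745) and stress (0.14) lists lost their calls. Without the animal block the ECM (adjusted p = 0.103), IGF (0.0759) and stress (0.0518) lists lost theirs.

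Mouse libraries also gave UMIs on the human genome. The human-genome matrices held 107, 127, 92 and 71 barcodes with 16102, 15159, 19175 and 16830 UMIs, or 1.79%, 5.28%, 4.52% and 3.10% of all UMIs of animals 1 to 4. Most of these barcodes, 107, 91, 79 and 70, were also in the mouse matrix. No barcode present in both had more than 8.04% of its UMIs on the human genome. TMSB4X, the human counterpart of a gene that is highly expressed in many mouse cells, gave the most human UMIs in each library, at 731, 651, 995 and 811.

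**Figure D4:**
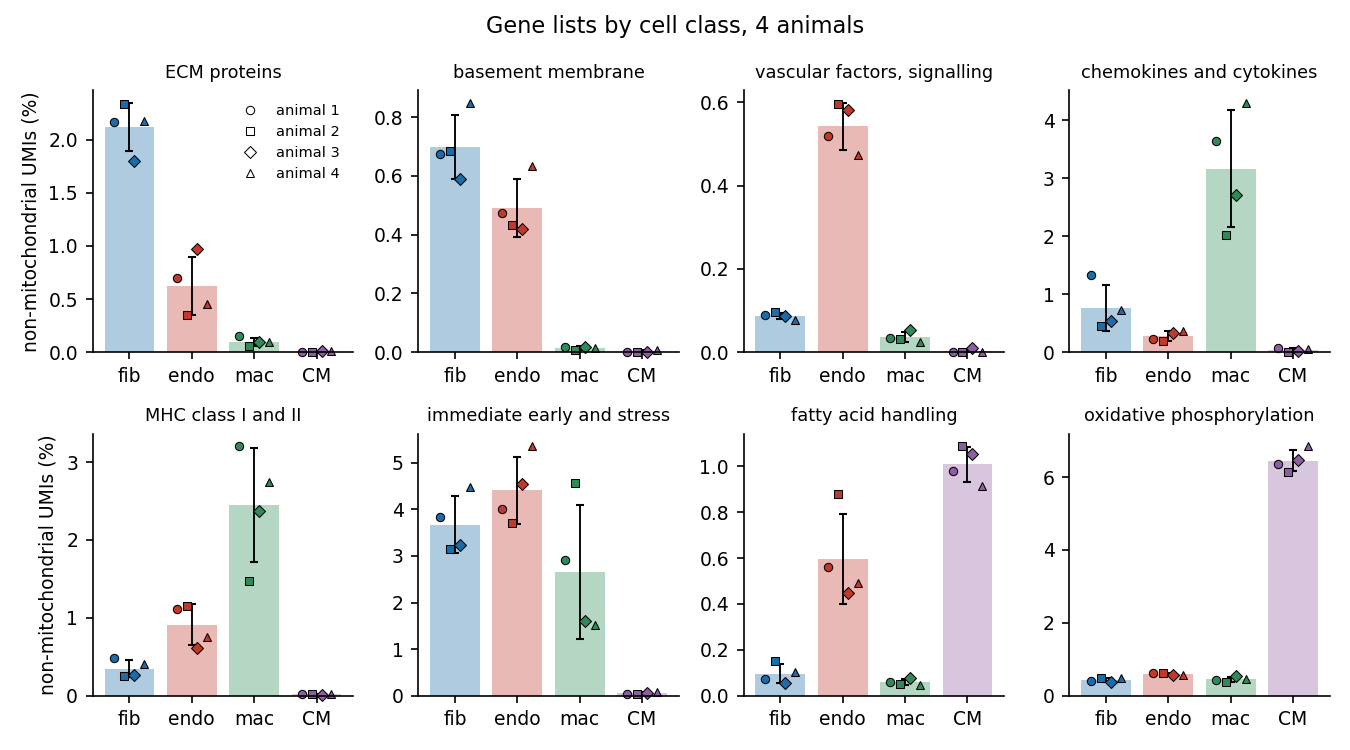
Percent of non-mitochondrial UMIs taken by 8 gene lists in fibroblast-like (fib), endothelial-like (endo), macrophage or monocyte-like (mac) and cardiomyocyte-like (CM) cells, with a point per animal and bars for mean and SD over 4 animals. Chemokines and cytokines took 3.17% on average in macrophage or monocyte-like cells and 0.761% in fibroblast-like cells, and oxidative phosphorylation genes took 6.45% in cardiomyocyte-like cells.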

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

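The 2 tests on free cardiomyocyte RNA, the test of doublets by gene lists, and those on cells without the reporter, on human cells and on barcodes with over 90% mitochondrial UMIs were chosen only after the result had been seen. All 4 libraries belong to 1 group, so no biological explanation was tested for any pattern below. A value stands here when 1 animal lay further from the other 3 than Dixon's 95% limit for 4 values or when a signal appeared in data outside the comparisons. Chance alone passes that limit in about 5% of groups, and here 15 of 142 groups (10.6%) passed it. Where the other 3 animals had 0, as for Clic5 and Scarb1 in fibroblast-like cells, any value above 0 passes the limit. Such groups are among the 15 and decide nothing.

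Animal 2 had 27.2% of its UMIs on mitochondrial genes, against 7.93 to 10.2% in the others, and the barcodes over 25% carried cardiomyocyte markers although no comparison used them. These markers took 1.16%, 0.976%, 7.84% and 6.29% of their non-mitochondrial UMIs in animals 1 to 4, against 0.0279%, 0.0122%, 0.0434% and 0.0504% in the kept cells outside the cardiomyocyte-like class. Of the barcodes over 25%, 2, 4, 3 and 1 in animals 1 to 4 lay under 90%. The one of animal 4 had 2307 UMIs, 690 detected genes and 35.3% mitochondrial UMIs. Whether any of these were cardiomyocytes removed by the filter was not tested. Barcodes with over 90% mitochondrial UMIs held 642, 1227, 489 and 621 non-mitochondrial UMIs. There the cardiomyocyte markers took 0.815% or more in each animal, with 2.66% and 2.90% in animals 3 and 4. The ratio was at least 41.7 in every animal, and 50.2 in those over 90%, which fits cardiomyocyte debris or mitochondria as a source. An even amount of free cardiomyocyte RNA per droplet would also take a larger share of barcodes with so few non-mitochondrial UMIs. The ratio therefore does not tell debris or mitochondria from free RNA. Damaged fibroblast-like, endothelial-like or macrophage-like cells were neither shown nor excluded: the ratio of their markers to the level in intact cells had a median of 0.339 (0.0846 to 1.05), and of 0.391 (0.240 to 0.990) in barcodes over 90%.

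In the 17 cardiomyocyte-like cells, of a population sorted as free of cardiomyocytes, the cardiomyocyte markers took at least 218 times the share of the other kept cells in each animal, but these markers helped to define the class, so that ratio decides nothing. Genes outside the clustering argue against free cardiomyocyte RNA that takes an even share of every droplet. In the sums per animal, the oxidative phosphorylation list took at least 9.93 times its highest share in the other 3 named classes. An even amount of free RNA per droplet takes a larger share of a shallow barcode. The ratio therefore decides nothing for the shallow barcodes of the class, such as those of 488, 683, 860 and 915 UMIs. Whether the barcodes of this class held whole cells or fragments was not tested. Doublets with a fibroblast-like, endothelial-like or macrophage-like cell were excluded as the source of the class in animals 3 and 4, each with 7 such cells, because the ECM, vascular and MHC lists, also outside the clustering, reached at most 0.0190 of their share in those classes; the ratio of 0.0134 for the class markers decides nothing. Whether cells without the reporter passed the sort could not be decided, because the matrices hold 0 tdTomato entries.

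The human-genome matrices held 16102, 15159, 19175 and 16830 UMIs for animals 1 to 4, where 3 UMIs would be the limit allowed by a count of 0. Human cells were excluded as the source, since no barcode of both matrices had more than 8.04% of its UMIs on the human genome, and the 0, 36, 13 and 1 barcodes of the human matrices alone had at most 0, 11, 13 and 22 UMIs. Mouse RNA assigned to human genes fits, because human UMIs per barcode rose with mouse UMIs in every library (lowest Spearman rho 0.861 across barcodes).

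The share of fibroblast-like cells was highest in animal 1, at 39.4% against 34.4 to 35.1%. The share of macrophage or monocyte-like cells was lowest in animal 2, at 15.6% against 27.6 to 29.3%. In fibroblast-like cells, Tnfaip6 stood at 1132 CPM in animal 1 (337 to 444 in the others) and Ccl2 at 2718 (312 to 580). Dpep1 stood at 1203 in animal 4 (715 to 782), and Zeb2 at 243 in animal 2 (99.7 to 111). Of the genes that were low in fibroblast-like cells, Clic5 was at 6.94 in animal 3 (0 in the others), Ecscr at 27.0 in animal 2 (0 to 3.05) and Scarb1 at 6.65 in animal 4 (0 in the others), with 1, 3 and 1 UMIs in all fibroblast-like sums together, so that few molecules set these animals apart. In endothelial-like cells, C3 was at 346 in animal 1 (0 to 39.5), Bst2 at 1001 in animal 2 (543 to 617) and Ly6a at 2550 in animal 2 (1139 to 1295). Endothelial-like cells of animal 3 were lowest in Tcf4, at 397 (604 to 644), and in Pcna, at 66.2 (127 to 137).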

How the results depend on the processing

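Leaving out cells with over 50% haemoglobin UMIs was chosen only after the result had been seen; all other alternatives were fixed before the data were examined. With few cells per class, changes near log2 1 can be missed, and Twist2 rests on 8 UMIs.

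The mean share of fibroblast-like cells was 21.5% with no cell filter, 22.1% with at least 500 detected genes, 21.2% at Leiden resolution 1.2 and 38.4% without Scrublet calls, against 35.8%. With no filter, endothelial-like cells made up 16.1%, macrophage or monocyte-like cells 18.2% and unnamed barcodes 39.7%, the last in clusters of 114 and 46 barcodes led by mitochondrial genes. Unnamed cells made up 13.5% with at least 500 genes and 19.4% at resolution 1.2, where a cluster with all 10 fibroblast markers detected stayed unnamed, because its top 10 genes held the Schwann marker Gpm6b and 0 fibroblast markers. There the fibroblast-like minus endothelial-like difference turned to −7.93 and −7.18 points. Twist2 averaged 8.29 CPM after thinning, against 3.73. Where no reason is given here, the cause was not tested.

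With no low-count filter, which tests 7389, 7151 and 7118 genes, 349 higher and 332 lower genes were called for fibroblast-like against endothelial-like cells, 522 and 450 for fibroblast-like against macrophage-like, and 380 and 435 for endothelial-like against macrophage-like. Of these, 328, 496 and 340 were shared with the main calls. Lists called rose to 13 and 11 in the pairs with fibroblast-like cells, and the mesenchymal and cardiac transcription factors turned to higher in fibroblast-like than macrophage-like cells (adjusted p = 0.00455), with more members measured. Fry called 11 lists for fibroblast-like against endothelial-like cells. With an estimated correlation, 0 lists were called in each pair.

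Without the replicate block the calls were 179 and 168, 266 and 235, and 181 and 195 genes, and 8, 7 and 5 lists. Leaving out the pairing ended the calls of Sparc and C3 (fibroblast-like against endothelial-like; adjusted p = 0.104 and 0.0631 without it), Timp2 and Cxcl1 (fibroblast-like against macrophage-like; 0.0710 and 0.191) and Hspa1a (endothelial-like against macrophage-like; 0.193). Without it the interferon list (fibroblast-like against macrophage-like) and the ECM, IGF and stress lists (endothelial-like against macrophage-like) were no longer called. The IGF list (fibroblast-like against endothelial-like, 0.0483) and the vascular list (fibroblast-like against macrophage-like, 0.0468) were newly called, and the block changed no other call of a named gene or list.

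Leave-one-out ranges were 34.1 to 36.3% fibroblast-like, 24.2 to 32.5% endothelial-like, 23.2 to 31.0% macrophage or monocyte-like, 6.44 to 10.2% cardiomyocyte-like and 0 to 4.54% unnamed cells, 3.01 to 12.1 points for fibroblast-like minus endothelial-like, and 2.49 to 4.97 Twist2 CPM. Genes higher and lower ranged from 121 to 188 and 117 to 160 (fibroblast-like against endothelial-like), 227 to 310 and 224 to 305 (fibroblast-like against macrophage-like), and 175 to 254 and 190 to 281 (endothelial-like against macrophage-like). Against macrophage-like cells the fits without animal 1, 3 or 4 hold 2 animals. Lists called ranged from 6 to 8, 7 to 10 and 6 to 8.

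Of the named genes, called or not in the main setting, 13 of 63, 7 of 63 and 5 of 58 lost a call under at least 1 alternative. Among genes called in the main or the alternative setting, 0 turned direction. Turns of genes called in neither were not counted. The haemoglobin alternative left 186 and 168, 265 and 250, and 175 and 193 genes. Fewer than 3 animals had class sums for fibroblast-like against endothelial-like cells at Leiden resolution 1.2 and without Scrublet calls, for fibroblast-like against macrophage-like at 1.2, and for endothelial-like against macrophage-like without Scrublet calls. Leaving out cells whose barcode is in the human matrix was not run, since it leaves 5 of 246 cells.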

Other observations

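The cardiomyocyte-like comparisons and the thinned count of cell cycle genes below were chosen only after the result had been seen. Cardiomyocyte-like cells, which sarcomere genes helped to define, had higher shares of the oxidative phosphorylation and fatty acid handling lists than the other 3 named classes in 4 of 4 animals. Mitochondrial oxidative phosphorylation genes took 6.45% ± 0.292 of their non-mitochondrial UMIs (SD, n = 4 animals), against 0.437% ± 0.0515 in fibroblast-like, 0.597% ± 0.0346 in endothelial-like and 0.453% ± 0.0648 in macrophage or monocyte-like cells. Cox6c, a subunit of cytochrome c oxidase, stood at 7359 ± 973 CPM, against 526, 668 and 438 in those classes, and the ATP synthase gene Atp5g1 at 7255 ± 2809. The fatty acid handling list took 1.01% in cardiomyocyte-like cells, against 0.0958%, 0.596% and 0.0595% in fibroblast-like, endothelial-like and macrophage or monocyte-like cells. Fabp3, the fatty acid binding protein of heart muscle, stood at 8046 ± 568 CPM in cardiomyocyte-like cells, and Acadm, an enzyme of fatty acid oxidation, at 1338 ± 325. Cd36 was at 223 ± 170, below the 1611 ± 558 of endothelial-like cells. Jund stood at 122 ± 111, Jun at 108 ± 115 and B2m at 110 ± 90.9, below the other 3 classes in 4 of 4 animals, and these single genes were not tested. Each difference in oxidative phosphorylation or fatty acid handling share had the smallest exact sign-flip p that 4 animals allow. This sign-flip p came to 0.130 after adjustment over 48 comparisons, so none could pass. Animals 1 and 2 had 1 and 2 cardiomyocyte-like cells.

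Cells with UMIs of at least 3 of 16 cell cycle genes numbered 10 of 67 endothelial-like (14.9%, exact 95% interval 7.40 to 25.7%), 10 of 66 macrophage or monocyte-like (15.2%, 7.51 to 26.1%) and 2 of 90 fibroblast-like cells (2.22%, 0.270 to 7.80%). In animals 1 to 4 they numbered 5, 1, 0 and 4, then 5, 2, 2 and 1, and 0, 0, 0 and 2 in these classes, and the intervals pool the animals. These cells were deeper than most, with medians of 13927, 10594 and 12546 UMIs. After thinning to 2000 UMIs the counts were 2 of 63, 4 of 63 and 1 of 82, so no difference in cycling is read from them.

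The class sums were also divided in every other way into groups of the same size. For fibroblast-like against endothelial-like cells, 8 of 32 splits part the 2 sums of every animal as the real one does, and 1 of them, the real one, gave the 358 genes called. The highest other split gave 0, as did the 24 splits that leave the sums of some animals on the same side, and 3 further splits could not be fitted. For fibroblast-like against macrophage-like cells 1 of 10 splits, the real one, gave the 531 genes and the highest other 0, and for endothelial-like against macrophage-like cells 1 of 10 gave the 368 genes and the highest other 0. In these pairs 4 splits part every animal, so all 3 comparisons have too few such splits for a share under 0.05.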
